A study of Mus musculus with 18 samples.

How the data were processed

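The series measured messenger RNA in mouse T cells and in the cells that presented antigen to them. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the Lexogen QuantSeq kit, which sequences the 3′ ends of transcripts, and sequencing was done on an Illumina NextSeq instrument. The 18 libraries form 6 groups of 3: P13.9 cells, a fibroblast line used as antigen-presenting cells, naive CD4+ T cells, and CD4+ T cells after 4 days with peptide at 0.01, 0.1, 1.0 or 10 µM. Groups were taken from the sample titles. The labels do not say whether the 3 samples of a group came from separate animals or cultures, so all p-values measure the spread between these samples.

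The deposited table holds 1 normalized signal value per gene and library, made by the authors with the median-of-ratios method, per the file headers and the submitters' processing notes. Those notes name FastQC 0.11.8, STAR 2.6.1d, HTSeq 0.9.1 and DESeq2, the last without a version, and the mm10 build. The annotation, the strand setting of the counting and the settings of each tool are not given in the sources used here. Dividing a whole read count by 1 factor per library leaves steps in the values, and these steps were used to recover the reads. Of 284544 values, 99.999% were whole reads within a tolerance of 1e-05 reads. The 1 exception was Tbx21 in the library naive 1, deposited as 1.31 where 1 read of that library is worth 6.55. How that value arose is not given, and comparisons of Tbx21 with naive cells were repeated with it missing, at 0 and at 1 read.

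The table has 15808 features, of which 110 carried no gene name. The unnamed features held 12.4% to 15.6% of the naive reads and 1.94% to 5.36% of the reads elsewhere, and they were left out of all tests. Of the named features, 13864 matched a symbol and 30 a synonym in a RefSeq annotation of GRCm38, the assembly also called mm10, and 1804 matched neither and kept the name in the table. Positions of genes come from that annotation.

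The recovered reads in named genes numbered 27789, 53280 and 97757 in the naive libraries, 201627 to 352001 in P13.9 and 156941 to 733009 in the activated T cell libraries. These totals lie far below the sequencing depth that the labels state. Reads carried no molecular identifiers as far as the sources say, so counting intervals cover counting error only. Correlations between replicates over genes were 0.581 to 0.757 in naive cells, 0.893 to 0.975 in activated cells and 0.933 to 0.952 in P13.9. No pair of libraries held identical values.

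Because the values are normalized, limma 3.58.1 in R 4.3.3 was the main test, with lmFit and eBayes with a mean-variance trend on log2(value + 1). Fold changes are on that scale, which understates changes of genes with low values. Genes with a value of at least 5 in at least 3 of the 15 T cell libraries were kept, 7264 in all, and the 5 T cell groups shared 1 estimate of the spread. The naive replicates agreed less than the others. A shared spread can therefore be too wide between doses and too narrow against naive cells. P13.9 was compared with naive cells in a fit of all 18 libraries with 8179 genes. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p below 0.05. The dose slope is the log2 change per 10-fold dose over the 4 doses. The dose curvature is the mean of 10 and 0.01 µM minus the mean of 1.0 and 0.1 µM. A negative value means a higher mean over the middle doses, which a low value at 1 end dose alone can also give. Where a gene had 1 to 3 reads in all libraries of a group, the ratio of reads per unit of depth is given with its exact 95% counting interval, and with no read a lower bound is computed from a floor of 3 reads over the group.

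Most comparisons, most of their tests, most alternatives and 26 gene lists were fixed before the data were examined. The list tests of the dose curvature were not in that fixed plan. Of the lists, 22 kept at least 5 genes and were tested with camera at a preset correlation of 0.01, adjusted over lists, beside camera with an estimated correlation and fry. The rule for named genes allowed 16 genes of T helper biology and T cell activation in every comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 and no overlap between groups, and the 4 members of each list with the smallest adjusted p. Which of the allowed genes are named was decided after their values were seen, leaving out most genes with 3 or fewer reads in a group and genes with near-identical copies. Il17a, Cxcr5 and Foxp3 were not analysed here, and some other allowed genes are not reported here.

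The activated T cells had been in contact with P13.9 cells, so a P13.9 transcript share was estimated per library as the median ratio of its values to the P13.9 mean. The planned rule, genes with a P13.9 mean of at least 200 and at most 1 in each naive library, gave 0 genes, as did a minimum of 1000. The fixed fibroblast list was used in its place, with its 7 genes that reached a P13.9 mean of 20, a limit set after the table was seen. A set of 74 genes with no read in any naive library was added as another estimate, which makes 4 definitions tried. The share times the P13.9 mean was also subtracted from the activated libraries. Plain subtraction moved the median change of all genes, so a version rescaled by 1 minus the share was added.

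The sample numbers in the labels fall into 2 runs, treated as a possible batch. Run 1 held P13.9, naive, 1.0 and 0.01 µM, and run 2 held 10 and 0.1 µM. The limma comparisons of doses within a run were not in the fixed plan. The log2 ratio of Tbx21 to Gata3 was taken with 1 added to each value. The slope of the P13.9 share and of that ratio was tested over the 12 activated libraries with 100000 permutations, two-sided. Differences between groups of 3 used a two-sided exact permutation test, whose smallest possible p is 0.1. Each count of called genes was also set against counts from other splits of the same libraries, all 10 for groups of 3 and 100 drawn splits for slope and curvature.

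Alternatives were pseudocounts of 4 and 0.5, no filter, a mean of at least 20, a log2 change of at least 1, TMM and quantile rescaling, robust eBayes, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, fits of only the groups compared or only the activated libraries, blocks for run and replicate letter, and each library left out in turn. Array weights, the added gene set, the rescaled subtraction, the slope without 0.01 µM, reads thinned to naive depth and the treatments of the Tbx21 value were added after the data were seen. The scripts were also tested on simulated libraries of the 10 versus 0.01 µM comparison with 6783 genes. There limma recovered 11% of genes changed 2-fold and 95% of those changed 4-fold, with 1 false call among 107. In the same simulation edgeR recovered 55% and 100% with 8 false among 163, and DESeq2 71% and 100% with 12 false among 183.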

Results

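Messenger RNA was measured by 3′ sequencing in mouse CD4+ T cells that carried the 5C.C7 T cell receptor, a transgenic receptor specific for a cytochrome c peptide. Naive cells from spleen and lymph node were activated for 4 days on P13.9 cells, a fibroblast line that presented the peptide pPCC at 0.01, 0.1, 1.0 or 10 µM. Naive CD4+ T cells and P13.9 cells were sequenced for comparison, which gives 6 groups of 3 libraries. The series asks how the strength of the T cell receptor signal shapes T helper differentiation, and its title names the transcription factors GATA3 and T-bet, the product of Tbx21. Recovered reads in named genes ran from 27789 to 97757 in the naive libraries, from 156941 to 733009 in the activated ones and from 201627 to 352001 in P13.9, and 1 read was worth a normalized value of 2.17 to 6.55 in naive cells. Levels below are mean normalized values ± SD with n = 3, and log2 changes are given ± the standard error of the limma fit with n = 3 per group.

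The first comparison sets the strongest against the weakest signal, 10 against 0.01 µM, for the factors that direct T helper fates. Tbx21, the regulator of T helper 1 cells on chromosome 11 at 97098007 to 97115331 of mm10, rose by a log2 change of 3.18 ± 0.38 (limma adjusted p = 0.000141). Its level was 1.04 ± 0.124 at 0.01 µM, 7.89 ± 2.37 at 0.1 µM, 9.72 ± 2.35 at 1.0 µM and 17.5 ± 1.56 at 10 µM. Gata3, the regulator of T helper 2 cells on chromosome 2 at 9857078 to 9887953, fell by a log2 change of -1.15 ± 0.21 (adjusted p = 0.00389), and its level was 81.6 ± 5.96, 71.0 ± 8.56, 62.0 ± 14.9 and 36.3 ± 4.30 from the lowest dose to the highest. Naive cells held 3.18 ± 1.63 of Tbx21, from 3 whole reads and 1 value of 0.2 of a read, and 45.8 ± 12.1 of Gata3. P13.9 held 0.223 of Tbx21, from 1 read, and 2.21 ± 0.984 of Gata3.

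The log2 ratio of Tbx21 to Gata3 was taken with 1 added to each value. At 0.01 µM that 1 nearly equals the Tbx21 level of 1.04, which raised the ratio there and lessened its change with dose. The ratio was -5.34 ± 0.05 (SD) at 0.01 µM, -3.05 ± 0.52 at 0.1 µM, -2.55 ± 0.66 at 1.0 µM and -1.01 ± 0.05 at 10 µM, beside -3.54 ± 1.00 in naive cells. Its slope was 1.35 per 10-fold dose over the 12 activated libraries, with a two-sided permutation p of 2e-05. The sample numbers fall into 2 runs, with 10 and 0.1 µM in one and 1.0 and 0.01 µM in the other, so that the end doses lie in different runs. The ratio differed by 2.04 between 10 and 0.1 µM and by 2.79 between 1.0 and 0.01 µM, each with an exact permutation p of 0.1, the smallest that groups of 3 allow. For Tbx21 alone the log2 change was 1.09 ± 0.38 for 10 against 0.1 µM (limma adjusted p = 0.632) and 2.38 ± 0.38 for 1.0 against 0.01 µM (adjusted p = 0.00242), and for Gata3 it was -0.95 (adjusted p = 0.152) and -0.42 (adjusted p = 0.36). The naive libraries, whose replicates agreed less, entered the spread used here, so a change without a call is not shown to be absent.

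**Figure D1:**
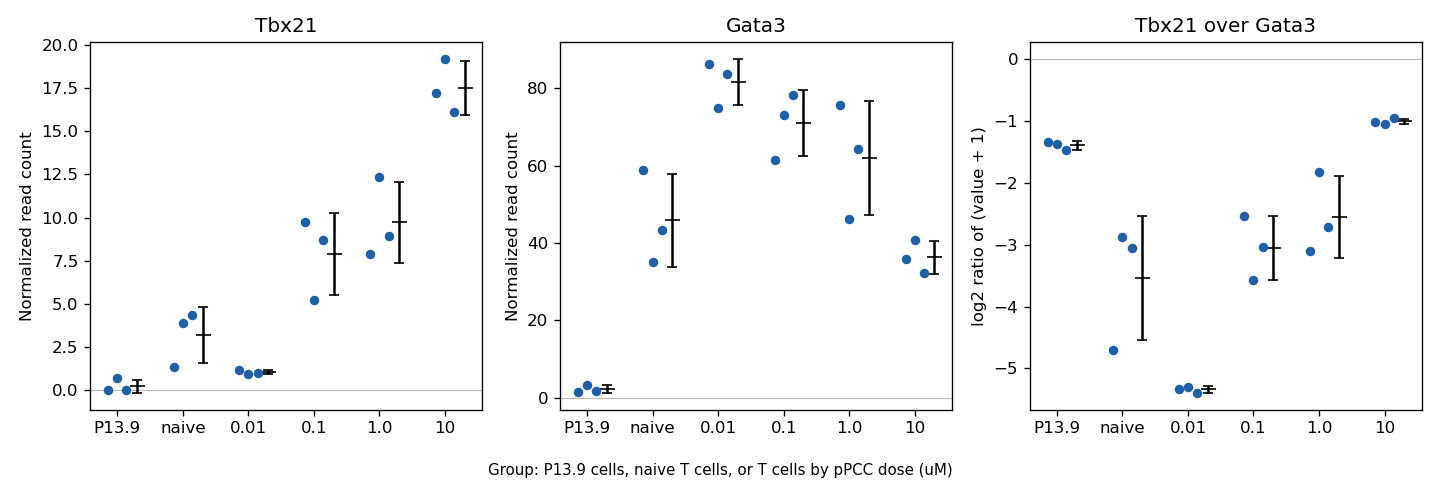
Normalized values of Tbx21 and of Gata3 per library (points, 3 per group) with the group mean and SD (bars), for P13.9 cells, naive T cells and T cells activated at 4 peptide doses in µM, on linear axes. Tbx21 runs from a mean of 1.04 at 0.01 µM to 17.5 at 10 µM, and Gata3 from 81.6 to 36.3.

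RNA of the presenting cells also differed between the doses. The P13.9 transcript share was 37.2 ± 9.08% of the P13.9 level at 0.01 µM, 9.75 ± 4.54% at 0.1 µM, 7.54 ± 2.58% at 1.0 µM and 2.65 ± 0.808% at 10 µM by the fibroblast list. Its 7 genes also had reads in naive cells, where the share was 4.99 ± 0.327%. By the 74 genes with no naive read it was 23.7 ± 3.03%, 7.43 ± 1.84%, 5.25 ± 1.97% and 2.76 ± 0.508% from the lowest dose to the highest. The absence of reads at the naive depth does not make a gene specific to P13.9. Most of the set fell with dose, but Ptms went from 13.5 at 0.01 µM to 20.1 at 10 µM and Ech1 from 12.1 to 17.0. The slope of the share was -10.6 points per 10-fold dose by the list (two-sided permutation p = 0.00014) and -6.50 points by the other set (p = 7e-05). Within the runs the list share differed by -7.11 points between 10 and 0.1 µM and by -29.7 points between 1.0 and 0.01 µM, each with an exact permutation p of 0.1, the smallest possible.

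**Figure D2:**
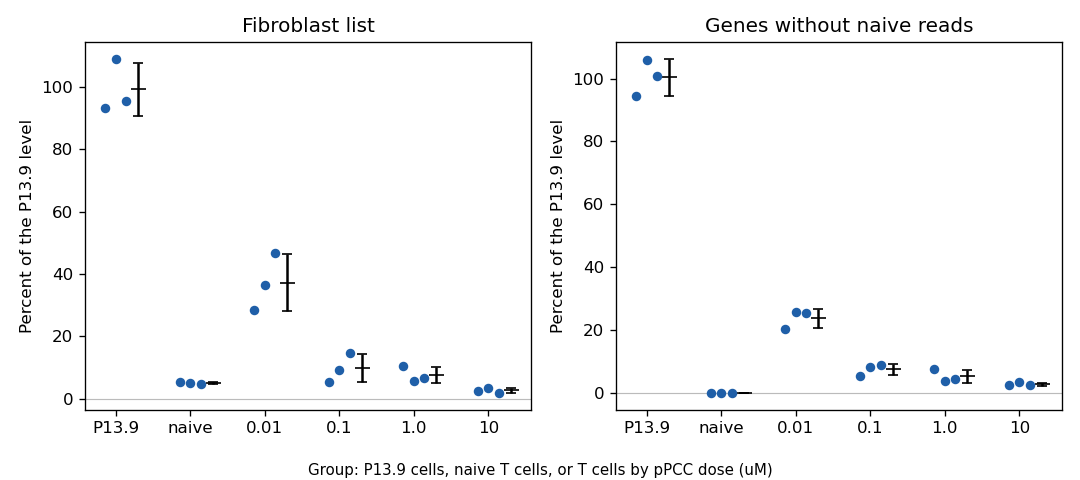
P13.9 transcript share per library in percent (points, 3 per group) with the group mean and SD (bars), on a linear axis, for P13.9 cells, naive T cells and T cells activated at 4 peptide doses in µM. The fibroblast-list share runs from 37.2% at 0.01 µM to 2.65% at 10 µM, beside 4.99% in naive cells.

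Several genes of the T helper 1 program rose with Tbx21 at 10 against 0.01 µM, where the P13.9 share was lower. Of 17 list members tested, 6 rose, 1 fell and 10 did not pass. Of these members, 10 passed when adjusted over the list alone (camera adjusted p = 0.000128, and adjusted p = 0.0729 with an estimated correlation). Cxcr3, a chemokine receptor of T helper 1 cells, held 13.8 ± 0.719 at 10 µM and 0.0558 at 0.01 µM (adjusted p = 1.38e-05). These levels came from 163 reads and 1 read, a ratio of 185 with a counting interval of 32.7 to 7347. Irf1, an interferon-induced transcription factor gene, rose by 1.04 ± 0.19 (adjusted p = 0.00369). The member that fell was Cxcr6, another chemokine receptor, with -2.00 (adjusted p = 0.00505). Of 17 interferon-stimulated genes, 4 rose and 13 did not pass, and 6 passed when adjusted over the list alone (camera adjusted p = 0.0074, and 0.0422 with an estimated correlation). Igtp, an interferon-inducible GTPase, rose by 1.95 ± 0.29 (adjusted p = 0.000706), from 12.9 ± 1.93 to 52.5 ± 4.07. The peptide transporter gene Tap1, also on that list, rose by 1.40 ± 0.19 (adjusted p = 0.000384). Psmb10, an immunoproteasome gene on no list, rose by 1.79 ± 0.27 (adjusted p = 0.000848). With the P13.9 share subtracted and the rest rescaled, the T helper 1 list had a camera adjusted p of 0.132 with the fibroblast-list share and 0.00566 with the added gene set. The interferon list had 0.408 and 0.104.

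Genes of the T helper 2 program fell beside Gata3 as the P13.9 share fell. Of 10 members tested, 4 fell, Gata3 among them, and 6 did not pass. Of these members, 5 passed when adjusted over the list alone (camera adjusted p = 0.0283, and adjusted p = 0.0729 with an estimated correlation). Maf, a transcription factor that drives Il4 expression, fell by -2.29 ± 0.28 (adjusted p = 0.000176) from 18.9 ± 3.80 to 3.09 ± 0.925. Epas1, a hypoxia-inducible factor, fell by -3.09 ± 0.74 (adjusted p = 0.0169) and the cytokine gene Il13 by -1.74 ± 0.43 (adjusted p = 0.0212), from 34.7 ± 4.43 to 10.1 ± 3.78. Icos, a costimulatory receptor gene of the follicular helper list, fell by -1.51 ± 0.33 (adjusted p = 0.00985). The Epas1 call was lost without 0.01 µM A, B or C or 10 µM A or B (adjusted p = 0.0614, 0.0696, 0.0559, 0.0850 and 0.0538). That of Il13 was lost without 0.01 µM A, B or C or 10 µM B (0.0813, 0.0549, 0.0747 and 0.117) and with a replicate block (0.0513). P13.9 cells held 0.773 of Maf, 0 of Epas1 and 3.79 of Il13. Of 7 T helper 17 genes, 3 fell and 4 did not pass, with 4 past the threshold when adjusted over the list alone (camera adjusted p = 0.000149, and 0.0345 with an estimated correlation). The 3 were the chemokine gene Ccl20 and the membrane protein genes Tmem176a, with -2.84 (adjusted p = 0.000266), and Tmem176b, with -2.25 (adjusted p = 0.00764). With the list share subtracted and rescaled, Tmem176a had -1.42 (adjusted p = 0.16) and Tmem176b 0.11 (adjusted p = 0.972). With the added-set share rescaled they had -2.91 (adjusted p = 0.00248) and -1.66 (adjusted p = 0.0882). Ccl20 held 93 reads at 0.01 µM and 1 read at 10 µM, a ratio of 82.0 with a counting interval of 14.4 to 3273 (adjusted p = 4.11e-06). The lists for follicular helper cells (camera adjusted p = 0.339) and regulatory T cells (0.556) were not called, and Bcl6, the regulator of follicular helper cells, gave 0.09 (adjusted p = 0.939).

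Some glycolysis and oxidative phosphorylation genes rose from 0.01 to 10 µM, again with the lower P13.9 share at 10 µM. In the glycolysis list, 9 of 25 genes rose, 1 fell and 15 did not pass, and 16 passed when adjusted over the list alone (camera adjusted p = 4.28e-10, and 0.0422 with an estimated correlation). The phosphofructokinase gene Pfkp rose by 1.32 ± 0.18 (adjusted p = 0.000384), the glucose transporter gene Slc2a1 by 1.36 ± 0.25 (adjusted p = 0.00349) and Mif by 1.23 (adjusted p = 0.00369). Of 28 oxidative phosphorylation genes, 4 rose, 1 fell and 23 did not pass, with 5 past the threshold when adjusted over the list alone (camera adjusted p = 0.000815, and 0.0729 with an estimated correlation). Chchd10, a gene for a mitochondrial protein on no list, rose by 2.17 ± 0.33 (adjusted p = 0.000814). Of 38 cell cycle genes, 3 rose and 35 did not pass, and adjusted over the list alone 3 passed (camera adjusted p = 0.00769, and 0.470 with an estimated correlation). After the rescaled subtraction this list was not called either, with its direction turned by the fibroblast-list share (0.408) and kept by the added set (0.649). Mcm3, a replication helicase gene, rose by 0.89 (adjusted p = 0.0073), and with the fibroblast-list share subtracted and rescaled its adjusted p was 0.119, and 0.0373 with the added set.

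Some receptor and signaling genes of T cells also rose with the lower P13.9 share at 10 µM. Of 14 chemokine receptor and homing genes, 6 rose, 1 fell and 7 did not pass, and 7 passed when adjusted over the list alone (camera adjusted p = 0.000333, and 0.0885 with an estimated correlation). Ccr7, a receptor for homing to lymph nodes, rose by 1.36 (adjusted p = 0.00516), with an adjusted p of 0.0948 after the rescaled subtraction of the fibroblast-list share and 0.0267 with the added set. The T cell identity list had 2 genes that rose, 1 that fell and 13 that did not pass, and 7 passed when adjusted over the list alone (camera adjusted p = 0.000333, and 0.0281 with an estimated correlation). After the rescaled subtraction this list was not called, with its direction turned by the fibroblast-list share (0.185) and kept by the added set (0.649). Lck, the kinase that starts receptor signaling, rose by 1.28 ± 0.19 (adjusted p = 0.000609), whereas Ptprc, the gene for the phosphatase CD45, fell by -1.14 (adjusted p = 0.0103, and 0.0529 without 10 µM B). Il2rb, a chain of the interleukin-2 receptor on the regulatory T cell list, rose by 1.20 ± 0.24 (adjusted p = 0.00642), from 74.8 ± 9.28 to 172 ± 12.7, with an adjusted p of 0.146 after the rescaled subtraction of the fibroblast-list share and 0.0405 with the added set. For Il2ra the change was -0.41 (adjusted p = 0.517), for Irf4 0.23 (adjusted p = 0.742) and for Nr4a1 -0.72 (adjusted p = 0.35). With array weights, which called 3334 genes here, Il2ra (-0.44, adjusted p = 0.00365) and Nr4a1 (-0.70, adjusted p = 0.0475) were called.

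Fibroblast genes and the chemokine genes Cxcl1, Cxcl2 and Ccl2 fell from 0.01 to 10 µM together with the P13.9 share. For Sparc, Col1a2 and the other list genes that set the fibroblast-list share, this joint fall is by construction. The share by the 74 genes with no naive read also fell, from 23.7% at 0.01 µM to 2.76% at 10 µM. Of 10 fibroblast genes, 9 fell from 0.01 to 10 µM and 1 did not pass, and adjusted over the list alone 9 passed (camera adjusted p = 1.93e-09, and 0.0128 with an estimated correlation). Sparc, a matrix protein gene, fell by -3.55 ± 0.32 (adjusted p = 1.47e-05) from 36.6 ± 5.1 to 2.26, beside 123 ± 10.8 in P13.9 and 5.65 ± 1.51 in naive cells. Col1a2, a collagen gene, fell by -3.57 ± 0.55 (adjusted p = 0.000884), and the cyclin gene Ccnd1 by -3.70 ± 0.34 (adjusted p = 1.56e-05). The neutrophil chemokine genes Cxcl2 and Cxcl1 fell by -5.00 ± 0.28 (adjusted p = 1e-07) and -4.81 ± 0.50 (adjusted p = 5.45e-05), and the monocyte chemokine gene Ccl2 by -4.36 ± 0.77 (adjusted p = 0.00276). At 0.01 µM Cxcl1 stood at 258 ± 43.8 and Cxcl2 at 151 ± 17.7, beside 52.9 ± 7.69 and 18.4 ± 1.63 in P13.9 alone, and Ccl2 at 213 ± 40.4 beside 101 ± 4.85. Cd44, an adhesion receptor gene, fell by -1.75 ± 0.18 (adjusted p = 4.42e-05). Of 8 myeloid and dendritic cell genes 3 fell and 5 did not pass, with 3 when adjusted over the list alone (camera adjusted p = 0.00108, and 0.0729 with an estimated correlation). Of 7 genes of MHC class II and costimulation 2 fell and 5 did not pass, with 3 when adjusted over the list alone (camera adjusted p = 0.0499, and 0.280 with an estimated correlation).

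In all, 592 of 7264 genes were called between 10 and 0.01 µM, 138 higher and 454 lower, with 1581 at an unadjusted p below 0.05. Of the 454 lower genes, 320 had a P13.9 mean above their mean at 0.01 µM, which is 70.5%, against 51.7% of all genes. The share of calls that were higher was 23.3%, and it was 44.5% with edgeR, 53.6% with DESeq2, 36.8% with quantile rescaling and 56.2% among genes with a mean of at least 20. With the P13.9 share subtracted it was 91.0% for the fibroblast list and 73.9% for the added set, and after rescaling 58.5% and 42.1%. Leaving out 1 library of the 6 gave 275 calls without 10 µM A to 387 without 10 µM C, and each of the 6 lowered the count by over 1.5 times.

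The steps between neighboring doses ask where along the dose range these changes lay. Between 0.01 and 0.1 µM, Gzma, the gene of a cytotoxic granule protease, rose by 3.28 ± 0.34 (limma adjusted p = 0.000107) from 8.16 ± 0.663 to 88.4 ± 14.1. The glucose transporter gene Slc2a3 rose by 2.84 ± 0.47 (adjusted p = 0.00437), Cmtm7 by 2.42 ± 0.24 (adjusted p = 8.64e-05) and Basp1 by 2.91 ± 0.36 (adjusted p = 0.000678). Tbx21 rose over this step by 2.09 ± 0.38 (adjusted p = 0.00728), while Gata3 had -0.20 (adjusted p = 0.685). Cxcr3 held 34 reads at 0.1 µM and 1 at 0.01 µM, a ratio of 65.8 with a counting interval of 11.04 to 2676 (adjusted p = 0.00213). Pfkp rose by 1.46 (adjusted p = 0.000678) and Slc2a1 by 1.67 (adjusted p = 0.00224). As the P13.9 share went from 37.2% to 9.75%, Cxcl2 fell by -3.23 (adjusted p = 2.26e-05) and Cxcl1 by -3.46 (adjusted p = 0.00224). Ccnd1 fell by -2.62 (adjusted p = 0.000871), Sparc by -2.15 (adjusted p = 0.00224) and Cd44 by -1.30 (adjusted p = 0.00126). Sparc is among the genes that set that share. In all 406 genes were called, 158 higher and 248 lower, a share of 38.9% higher beside 56.5% with DESeq2 and 65.5% among genes with a mean of at least 20. With the P13.9 share subtracted it was 91.9% for the fibroblast list and 78.2% for the added set, and after rescaling 66.3% and 53.9%. This step crosses the runs, and leaving out any of its 6 libraries lowered the count by over 1.5 times, to between 88 without 0.01 µM B and 223 without 0.1 µM C.

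No gene was called by limma between 0.1 and 1.0 µM, where 110 genes had an unadjusted p below 0.05, and edgeR and DESeq2 also called 0. Between 1.0 and 10 µM, 6 genes were called, 1 higher and 5 lower, with 380 at an unadjusted p below 0.05, and edgeR called 175, DESeq2 181 and limma with array weights 145. Gzma fell by -4.10 ± 0.34 (adjusted p = 2.76e-05), from 91.5 ± 27.3 to 4.38 ± 1.37, and Maf fell by -2.30 ± 0.28 (adjusted p = 0.00254), from 19.3 ± 5.77 to 3.09 ± 0.925. Igtp rose by 1.91, Id2, an inhibitor of E proteins, fell by -1.39, the calcium-binding protein gene S100a6 by -1.32 and Cxcr6 by -2.56, each with an adjusted p of 0.0156. Leaving out 1 library gave 2 to 4 calls, 3 without 1.0 µM A or B, 2 without 10 µM A or B and 4 without 1.0 µM C or 10 µM C. The calls of Gzma and Maf held in every such fit, while the highest adjusted p was 0.127 for Igtp, 0.138 for Id2, 0.127 for S100a6 and 0.121 for Cxcr6. Quantile rescaling also ended the calls of Id2 (adjusted p = 0.0658) and S100a6 (0.0853). Plain subtraction of the fibroblast-list share ended that of S100a6 (0.102), which held after rescaling (0.0395). This step too crosses the runs.

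Several genes had a higher mean over the middle doses than over the end doses, as the curvature over the 4 doses measured. A low value at 1 end dose alone can also give this. Pfkp, for example, rose from 0.01 µM to both 0.1 and 10 µM. Gzma stood at 88.4 ± 14.1 at 0.1 µM and 91.5 ± 27.3 at 1.0 µM, against 8.16 ± 0.663 and 4.38 ± 1.37 at the ends, a curvature of -3.69 ± 0.24 (limma adjusted p = 9.67e-07). Basp1 had -2.47 ± 0.26 (adjusted p = 0.000221), Slc2a3 -2.02 ± 0.33 (adjusted p = 0.00968), Cmtm7 -1.68 ± 0.17 (adjusted p = 0.000179) and S100a6 -1.18 (adjusted p = 0.00156). Bcl3, a modulator of NF-kappa-B, had -1.10 and Pfkp -0.80, both with an adjusted p of 0.00828, and Slc2a1 was called too (adjusted p = 0.0137). Of the 25 glycolysis genes, 4 were called with a higher mean over the middle doses and 21 did not pass. Adjusted over the list alone 14 passed (camera adjusted p = 1.35e-16, and 0.0194 with an estimated correlation). Of 14 chemokine receptor and homing genes 4 did, with 10 when adjusted over the list alone (camera adjusted p = 1.30e-11, and 0.0194 with an estimated correlation). The T helper 2 list, with 2 of 10 genes called and 3 when adjusted over the list alone, had a camera adjusted p of 0.0023, and 0.0257 with an estimated correlation. The T cell identity list, with 0 of 16 called and 1 when adjusted over the list alone, had 0.000587, and 0.0209 with an estimated correlation. In both the mean over the middle doses lay above that over the end doses, which alone does not show a peak there. From 0.01 to 10 µM the T helper 2 list fell (mean log2 change -0.78) and the T cell identity list rose (0.41). The P13.9 share was itself uneven over the doses, with 37.2%, 9.75%, 7.54% and 2.65% from the lowest to the highest. These list tests of the curvature were not in the fixed plan. Ribosome biogenesis genes had a higher mean over the end doses with 0 of 23 called (0.000587, and 0.0445 with an estimated correlation). So did fibroblast genes with 0 of 10 called (0.0304, and 0.250 with an estimated correlation), through the 0.01 µM values. The 7 of them used for the P13.9 share were highest at 0.01 µM and lowest at 10 µM among the doses. Sparc, for example, held 36.6, 7.46, 6.82 and 2.26 from the lowest dose to the highest.

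**Figure D3:**
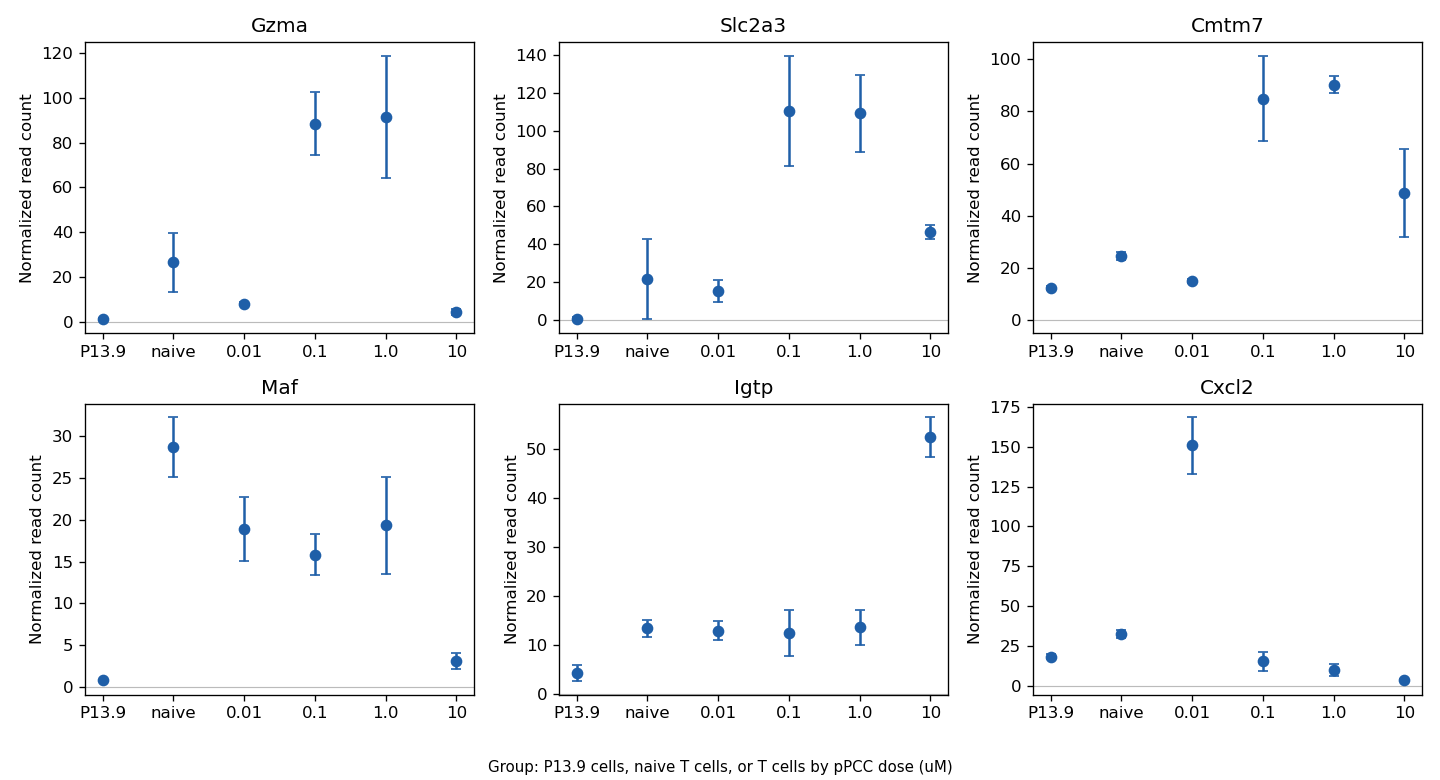
Group means of normalized values with SD (bars, n = 3) of Gzma, Slc2a3, Cmtm7, Maf, Igtp and Cxcl2 in P13.9 cells, naive T cells and T cells activated at 4 peptide doses in µM, 1 panel per gene on a linear axis. Gzma is near 90 at 0.1 and 1.0 µM and below 9 at 0.01 and 10 µM, and Cxcl2 runs from 151 at 0.01 µM to 3.74 at 10 µM.

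The curvature is balanced over the runs, with 1 end dose and 1 middle dose in each. It called 55 genes, 10 with a lower mean over the middle doses and 45 with a higher one. Quantile rescaling gave 38.8% of the calls on the former side against 18.2%. Leaving out 1 library gave 21 to 51 calls, and the count fell by over 1.5 times without any library at 0.01 or 10 µM, 0.1 µM A or B, or 1.0 µM C. Slc2a1 was not called without 0.01 µM A, 0.1 µM A, 1.0 µM C or 10 µM A (adjusted p = 0.0553, 0.0572, 0.0510 and 0.0553).

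The dose slope asks which genes followed the peptide dose across the whole range. Cxcr3 rose by 1.19 (limma adjusted p = 1.47e-05) and Tbx21 by 0.98 ± 0.12 (adjusted p = 0.000189) per 10-fold dose. Chchd10 rose by 0.64 (adjusted p = 0.00165), Igtp by 0.60 (adjusted p = 0.00101) and Psmb10 by 0.53 (adjusted p = 0.0017). Cxcl2 fell by -1.56 (adjusted p = 1.26e-07), Ccnd1 by -1.15 (adjusted p = 2.21e-05), Maf by -0.66 ± 0.09 (adjusted p = 0.000362) and Gata3 by -0.37 ± 0.07 (adjusted p = 0.00428). The glycolysis list rose with dose (camera adjusted p = 7.47e-11, and 0.0297 with an estimated correlation), as did the T helper 1 list (6.62e-05, and 0.0755 with an estimated correlation). The curvature was negative for 24 of 25 glycolysis genes, so their mean over the middle doses stood above that over the end doses, partly through low values at 0.01 µM. The T helper 2 list fell (0.024, and 0.0755 with an estimated correlation), and the P13.9 share fell by 10.6 points per 10-fold dose. In all 474 genes were called, 101 higher and 373 lower, a share of 21.3% higher, beside 44.2% with edgeR, 53.1% with DESeq2, 33.0% with TMM, 32.3% with quantile rescaling and 55.6% among genes with a mean of at least 20. With the P13.9 share subtracted it was 92.0% for the fibroblast list and 75.8% for the added set, and after rescaling 60.3% and 43.4%.

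The slope was also fitted without the 0.01 µM libraries, a setting chosen after the data were seen. There 3 genes were called, Maf and Igtp among them. Without that dose Tbx21 had 0.55 per 10-fold dose (adjusted p = 0.961), Gata3 -0.47 (adjusted p = 0.378) and Cxcr3 an adjusted p of 0.526. The naive libraries stayed in that fit and entered its estimate of the spread. Each 10 µM library held more Tbx21 (16.1 at the lowest) than any at 0.1 µM (9.76 at most) or 1.0 µM (12.4 at most). Gata3 was lower in each 10 µM library (40.8 at most) than in any at those 2 doses (46.1 at the lowest). Maf had -2.06 for 10 against 0.1 µM (adjusted p = 0.00963) and 0.01 for 1.0 against 0.01 µM (adjusted p = 1), which are the comparisons within the runs. For Igtp these values were 2.06 (adjusted p = 0.00963) and 0.04 (adjusted p = 0.984). Those of Ccnd1 were -1.08 (adjusted p = 0.528) and -3.00 (adjusted p = 0.000227), and those of Cxcl2 -1.77 (adjusted p = 0.0192) and -3.79 (adjusted p = 4.93e-06). In the fit of all T cell groups 7 genes were called between 10 and 0.1 µM and 312 between 1.0 and 0.01 µM. Leaving out 1 library gave 234 dose slope calls without 10 µM B to 505 without 1.0 µM B, and the count fell by over 1.5 times without any library at 0.01 or 10 µM.

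Activated cells were also compared with naive cells. No T cells cultured without peptide were sequenced, so this comparison joins activation with 4 days of culture on P13.9 cells. At 10 µM, Mcm3 rose by 2.53 ± 0.18 (limma adjusted p = 2.17e-08) from 14.8 ± 4.27 to 88.6 ± 6.88. In the cell cycle list 30 of 38 genes rose and 8 did not pass (30 when adjusted over the list alone, camera adjusted p = 1.99e-09, and adjusted p = 0.117 with an estimated correlation). Of 25 glycolysis genes 19 rose, 1 fell and 5 did not pass (20 when adjusted over the list alone, camera adjusted p = 5.79e-06, and 0.117 with an estimated correlation), with Pfkp at 2.41 ± 0.18 (adjusted p = 3.58e-08). Of 28 oxidative phosphorylation genes 23 rose, 1 fell and 4 did not pass (24 when adjusted over the list alone, camera adjusted p = 6.93e-07, and 0.0833 with an estimated correlation), with the malate dehydrogenase gene Mdh2 at 2.27 ± 0.15 (adjusted p = 1.16e-08). Of 17 cholesterol synthesis genes 7 rose and 10 did not pass (7 when adjusted over the list alone, camera adjusted p = 0.0283, and 0.117 with an estimated correlation). The immunoproteasome gene Psmb8 rose by 3.14 ± 0.28 (adjusted p = 2.29e-07), Il2ra by 1.40 ± 0.32 (adjusted p = 0.00166) and Il2rb by 1.37 ± 0.24 (adjusted p = 0.0002). For Tbx21 the change was 2.23 (adjusted p = 0.000143), a ratio of 4.99 with a counting interval of 1.68 to 24.4 from 201 against 3 reads. Gata3 had -0.30 ± 0.21 (adjusted p = 0.242), with 0.66 under TMM rescaling (adjusted p = 0.0126).

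Genes of resting cells fell at the same time. Of 26 naive and quiescence genes 16 fell, 1 rose and 9 did not pass (18 when adjusted over the list alone, camera adjusted p = 0.000421, and adjusted p = 0.117 with an estimated correlation). S1pr1, a receptor for exit from lymph nodes, fell by -3.25 ± 0.27 (adjusted p = 1.05e-07) from 128 ± 5.51, the antiproliferative gene Btg1 by -4.84 ± 0.39 (adjusted p = 8.67e-08) and Bcl6 by -2.74 ± 0.38 (adjusted p = 2.33e-05). The orphan receptor gene Nr4a1, an early gene of receptor signaling, fell by -5.54 ± 0.42 (adjusted p = 3.96e-08) from 136 ± 20.4, and Maf by -2.88 ± 0.28 (adjusted p = 6.07e-07). Of 14 genes induced by tissue dissociation 11 fell and 3 did not pass (11 when adjusted over the list alone, camera adjusted p = 9.17e-05, and 0.117 with an estimated correlation), among them Fos with -5.61 ± 0.32. Of 8 myeloid and dendritic cell genes 7 fell and 1 did not pass (7 when adjusted over the list alone, camera adjusted p = 0.000159, and 0.117 with an estimated correlation). S100a8, a gene of neutrophils, stood at 483 ± 69.8 in naive cells and fell by -6.74 ± 0.30 (adjusted p = 2.04e-10). All 9 mitochondrially encoded genes tested fell (9 when adjusted over the list alone, camera adjusted p = 3.16e-06, and 0.117 with an estimated correlation). Mitochondrial reads made up 15.4 ± 0.476% in naive cells against means of 3.24% to 4.45% in the other groups.

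The T helper lists were not called against naive cells at 10 µM, with camera adjusted p of 0.974 for T helper 1 (3 rose, 6 fell, 8 did not pass), 0.805 for T helper 2, 0.576 for T helper 17, 0.428 for follicular helper and 0.615 for regulatory T cells. Nor were interferon-stimulated genes (8 rose, 4 fell, 5 did not pass, 0.0985), chemokine receptors (0.680), T cell identity (0.560), ribosome biogenesis (0.561), apoptosis (0.680), fibroblast genes (0.629) or MHC class II genes (0.656). In all 4145 genes were called at 10 µM, 1765 higher and 2380 lower. At 1.0 µM 1692 were higher and 2281 lower, 3973 in all, and at 0.1 µM 1808 were higher and 2285 lower, 4093 in all. The share of higher calls at 10 µM was 42.6%, and it was 68.2% with TMM, which moved the median of all genes to 0.73, and 54.1% with quantile rescaling, with a median of 0.21. It was 54.0% with edgeR and 56.7% among genes with a mean of at least 20. At 1.0 µM the share was 42.6% beside 69.2% with TMM and 54.7% with quantile rescaling or edgeR, and 57.3% among genes with a mean of at least 20. At 0.1 µM it was 44.2% beside 68.2% with TMM, 54.5% with quantile rescaling, 55.4% with edgeR and 57.2% among genes with a mean of at least 20.

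At 1.0 and 0.1 µM, genes of growth, of resting cells, of early receptor signaling and of neutrophils were likewise compared with naive cells. Mcm3 rose by 2.30 ± 0.18 at 1.0 µM and by 2.33 at 0.1 µM, and Pfkp by 2.55 ± 0.18 and 2.54. At the same doses S1pr1 fell by -3.16 and -3.36, Nr4a1 by -6.19 and -5.81, and S100a8 by -6.12 and -5.59, each past the threshold of limma at an adjusted p below 0.05. For Tbx21 the change was 1.43 at 1.0 µM (adjusted p = 0.00518), a ratio of 2.88 with a counting interval of 0.952 to 14.3, and 1.14 at 0.1 µM (adjusted p = 0.0186), a ratio of 2.50 with an interval of 0.815 to 12.5. With the naive 1 value of Tbx21 missing, its adjusted p was 0.0273 at 1.0 µM and 0.0945 at 0.1 µM, and with that value at 1 read it was 0.0403 and 0.156. The Tbx21 call at 0.1 µM was also lost without 0.1 µM A (0.0743) or C (0.0586) and with DESeq2 (0.0695), and array weights ended it at 0.1 µM (0.154) and at 1.0 µM (0.127). Gata3 rose by 0.65 ± 0.21 at 0.1 µM (adjusted p = 0.0186), a call lost without naive 2 (0.0745), 0.1 µM B (0.0525) or 0.1 µM C (0.0678) and with array weights (0.0856). At 1.0 µM its change was 0.43 (adjusted p = 0.102), which was past the threshold at 0.63 without naive 1 (0.0133) or 1.0 µM B (0.0256). Gata3 at 1.0 µM was also called at 1.36 with TMM (4.51e-05), 1.16 with edgeR (0.000573), 1.09 with DESeq2 (0.00126) and 0.74 with quantile rescaling (0.0171).

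At 0.01 µM, the weakest signal, Gata3 rose against naive cells by 0.85 ± 0.21 (limma adjusted p = 0.00434) and Il2ra by 1.81 ± 0.32 (adjusted p = 0.000269). Irf1 fell by -1.79 ± 0.19 (adjusted p = 2.2e-06), and for Tbx21 the change was -0.95 (adjusted p = 0.0501). The 14 Tbx21 reads against 3 gave a ratio of naive over 0.01 µM of 3.26 with a counting interval of 0.601 to 11.7. The naive 1 value decided this call, with -0.54 (adjusted p = 0.404) for that value at 0, -1.52 (adjusted p = 0.00159) at 1 read and -1.33 (adjusted p = 0.00241) without the library. Quantile rescaling gave -1.59 (adjusted p = 0.000681). Of 38 cell cycle genes 30 rose and 8 did not pass (30 when adjusted over the list alone, camera adjusted p = 6.32e-09, and 0.131 with an estimated correlation). Of 28 oxidative phosphorylation genes 19 rose and 9 did not pass (19 when adjusted over the list alone, camera adjusted p = 9.44e-06, and 0.0831 with an estimated correlation). Of 25 glycolysis genes 10 rose, 3 fell and 12 did not pass (13 when adjusted over the list alone, 0.0197, and 0.439 with an estimated correlation). Of 17 cholesterol synthesis genes 5 rose and 12 did not pass (5 when adjusted over the list alone, 0.0305, and 0.0831 with an estimated correlation). Of 26 naive and quiescence genes 17 fell, 1 rose and 8 did not pass (19 when adjusted over the list alone, 2.79e-05, and 0.0831 with an estimated correlation), among them S1pr1 with -4.34 and Klf2 with -4.88. The 9 mitochondrially encoded genes all fell (1.89e-07), as did 13 of 14 dissociation genes (9.44e-06) and 7 of 8 myeloid genes (0.000249), each 0.0831 with an estimated correlation. The T helper 1 list (2 rose, 8 fell, 7 did not pass, 0.0982) and the T helper 2 list (3 rose, 7 did not pass, 0.133) were not called.

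Fibroblast genes and the chemokine genes Cxcl1 and Ccl2 rose at 0.01 µM against naive cells. Of 10 fibroblast genes 8 rose, 1 fell and 1 did not pass (9 when adjusted over the list alone, camera adjusted p = 0.00945, and adjusted p = 0.131 with an estimated correlation), beside the P13.9 share of 37.2% at this dose. With the fibroblast-list share subtracted and rescaled, the list had a camera adjusted p of 0.917 and turned downward, by construction since its genes set that share. Cxcl1 rose by 4.54 ± 0.50 (adjusted p = 2.83e-06) and Ccl2 by 5.22 ± 0.77. Sparc rose by 2.52 ± 0.32 (adjusted p = 1.21e-05), and with the share of the added gene set subtracted it had 0.36 (adjusted p = 0.516). In all 3588 genes were called, 1578 higher and 2010 lower. The share of higher calls was 44.0%, and it was 73.6% with TMM, 55.2% with quantile rescaling, 58.0% with edgeR, 51.7% among genes with a mean of at least 20, and 17.7% or 26.1% with the list or added-set share subtracted.

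P13.9 cells were compared with naive T cells to see which transcripts the presenting cells could bring into the other libraries. Gdf15, a stress-induced growth factor gene, held 198 ± 4.76 in P13.9 and no read in naive cells, at least 57.7-fold higher against a floor of 3 reads over the group (limma adjusted p = 2.12e-12). Sparc was higher by 4.24 ± 0.27 (adjusted p = 3.93e-10). Trac, a receptor alpha chain gene of T cells, was lower by -5.90 ± 0.21 (adjusted p = 8.13e-13), Gata3 by -3.87 (adjusted p = 3.34e-10) and Maf by -4.06 (adjusted p = 1.53e-09). S1pr1 held 113 reads in naive cells and none in P13.9, at least 219-fold lower in P13.9 (adjusted p = 2.14e-12). In all 4826 of 8179 genes were called, 2444 higher and 2382 lower, a share of 50.6% higher beside 66.8% with TMM, which moved the median of all genes from 0.16 to 0.61.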

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

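Array weights, the added gene set, rescaling after subtraction, thinning to naive depth and the slope without 0.01 µM were settings chosen after the data were seen. The log2 ratio of Tbx21 to Gata3 rose with dose and the P13.9 transcript share fell with dose in every setting run for them, and the depth of the naive libraries limits what can be seen against them. Counts not given here lay within 1.5 times those of the report. Where no reason is given, the cause was not tested.

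Fewer genes or fewer reads gave fewer calls by construction. With a mean of at least 20, the calls were 970 at 10 µM, 936 at 1.0 µM, 952 at 0.1 µM and 844 at 0.01 µM against naive cells, and 949 for P13.9. They were 251 for 10 against 0.01 µM, 249 for 0.1 against 0.01 µM and 189 for the dose slope, but 106 for the curvature. With activated reads thinned to naive depth, the 4 doses from 10 to 0.01 µM gave 2614, 2385, 2459 and 2019 calls against naive cells. A log2 change of at least 1 left 26 calls for the slope and 27 for the curvature. No filter gave 5504 calls for 0.01 µM against naive cells, 725 for the slope and 33 for the curvature, and a pseudocount of 4 gave 96 for the curvature.

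Count models and library weights called more genes between doses. In the simulated libraries the share of false calls was 0.935% with limma, 4.91% with edgeR and 6.56% with DESeq2, and limma recovered the fewest 2-fold changes. Those libraries were drawn with the same extra spread for every gene and no difference in P13.9 RNA. They therefore do not tell which of the counts below is nearer the truth. For 10 against 0.01 µM, 10 against 1.0 µM, 0.1 against 0.01 µM, slope and curvature, edgeR called 2528, 175, 1744, 2127 and 611 genes. DESeq2 called 2330, 181, 1543, 1976 and 570, and limma with array weights 3334, 145, 2340, 2941 and 1043. Quantile rescaling gave 703 calls for 0.1 against 0.01 µM and 103 for the curvature.

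Fits of fewer libraries estimate the spread from those libraries alone. Between doses they leave out the naive libraries, whose replicates agreed less. With only the compared groups fitted, limma called 2547 genes for 10 against 0.01 µM, 1402 for 0.1 against 0.01 µM and 2 for 10 against 1.0 µM, and 2534 and 2348 for 1.0 and 0.01 µM against naive cells. The fit of all T cell groups called 592, 406, 6, 3973 and 3588 in the same order. With only the 12 activated libraries the slope had 1680 calls and the curvature 552, and with the runs as a block the curvature also had 552 and the slope 373.

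Within the runs, fitted apart, the slope had 5 calls for 10 against 0.1 µM and 958 for 1.0 against 0.01 µM. Over the 3 higher doses it had 3 calls, in a fit that kept the naive libraries. The log2 ratio of Tbx21 to Gata3 changed by 1.02 and 1.40 per 10-fold dose within the runs, where the smallest exact permutation p is 0.1.

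Subtracting the P13.9 share gave 1339 calls for 10 against 0.01 µM, 1043 for 0.1 against 0.01 µM, 1125 for the slope and 292 for the curvature. After rescaling, 0.1 against 0.01 µM had 635 and the curvature 173, and with the added set the curvature had 179, or 113 rescaled. For 10 against 0.01 µM and for the slope, 7 and 7 gene lists were called after subtraction, 7 and 7 after rescaling, and 7 and 7 with the added set rescaled, against 12 and 12. Sparc at 0.01 µM against naive cells reversed from 2.52 to -2.71 with and without rescaling, by construction since it sets the share. Tmem176b for 10 against 0.01 µM went from -2.25 to 0.33, or 0.11 rescaled, but had -1.36 and -1.66 with the added set. After rescaling, lists that reversed had a camera adjusted p of 0.917 for fibroblast genes at 0.01 µM against naive cells, 0.408 for the cell cycle at 10 against 0.01 µM and also along the slope, and 0.185 and 0.175 for T cell identity there.

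With an estimated correlation 0 of 8 lists were called at 10 µM against naive cells, 0 of 9 at 0.01 µM, 5 of 12 for 10 against 0.01 µM and 5 of 12 for the slope. With fry, which compares a list with no change and not with other genes, 17 lists were called at 10 µM and 17 at 0.01 µM against naive cells, and 13 for 10 against 0.01 µM and for the slope.

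Leaving out 1 library at a time gave 275 to 387 calls for 10 against 0.01 µM, 2 to 4 for 10 against 1.0 µM, 88 to 223 for 0.1 against 0.01 µM, 234 to 505 for the slope and 21 to 51 for the curvature. With a replicate block of the letters A to C, the counts were 402, 5, 189, 314 and 23 for the same comparisons, and the adjusted p was 0.0513 for Il13 at 10 against 0.01 µM and 0.0746 for S100a6 at 10 against 1.0 µM. Over 18 pairs of libraries with the same letter, the correlation of their deviations from the group means was -0.197 at the lowest and averaged -0.041, against 0.020 for other pairs, and 3 pairs passed 0.1. For comparisons with naive or P13.9 cells, no paired analysis was possible because their columns carry numbers and not letters.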

Other observations

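The tests of P13.9 RNA, of dilution and of TMM rescaling were chosen after the results were seen. The lists of the unfolded protein response and of receptor signaling were not called by camera between 10 and 0.01 µM. Of 16 unfolded protein response genes, 4 fell from 0.01 to 10 µM and 12 did not pass, and adjusted over the list alone 4 passed (camera adjusted p = 0.359). By fry, which tests a list against no change, the list was lower at 10 µM (adjusted p = 0.00227) and fell along the dose slope (adjusted p = 0.00177). The chaperone gene Hsp90b1 fell by -0.99 (limma adjusted p = 0.00679), with an adjusted p of 0.242 after plain subtraction of the fibroblast-list share and 0.0587 with the added set, but 0.00985 and 0.0104 after rescaling. Against naive cells at 10 µM, 6 of these genes rose, 6 fell and 4 did not pass (camera adjusted p = 0.874). Of 22 genes induced by the T cell receptor, 2 fell from 0.01 to 10 µM, namely Cd44 with -1.75 ± 0.18 (adjusted p = 4.42e-05) and Egr3, an early growth response gene, with -1.86 (adjusted p = 0.00583), while 20 did not pass and adjusted over the list alone 2 passed (camera adjusted p = 0.561). Against naive cells at 10 µM, 4 of them rose, 12 fell and 6 did not pass (camera adjusted p = 0.205), and the activation marker gene Cd69 fell by -3.90 ± 0.33. The P13.9 share was 37.2% at 0.01 µM and 2.65% at 10 µM.

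Between 10 and 0.01 µM, lists without a call were naive and quiescence genes (5 rose, 1 fell, 20 did not pass, camera adjusted p = 0.303), cholesterol synthesis (0.359), ribosome biogenesis (0.943), apoptosis (0.353), mitochondrially encoded genes (0.943) and dissociation genes (0.876). The lists for B cells, CD8 T and natural killer cells, inhibitory receptors, and erythroid cells and platelets had fewer than 5 genes left and were not tested. Il13 was tested, but the cytokine genes Ifng, Il4, Il5, Il21 and Il2 had few reads at day 4. Over the 3 libraries of a group, Ifng had 5 reads in naive cells and 6, 1, 3 and 4 from 0.01 to 10 µM, and Il4 had 0 and then 2, 0, 0 and 4. Il5 had 5 and then 19, 6, 17 and 6, Il21 had 0 and then 19, 9, 10 and 2, and Il2 had 6 and then 15, 7, 3 and 35, so that no test of these was made at this depth. These reads are not scaled for depth, which was lowest in naive cells. Scaled, Ifng was 5.07 ± 4.52 in naive cells against 0.102 to 0.452 at the doses, and Il5 7.39 ± 7.84 against 0.464 to 1.88. Of the 35 Il2 reads at 10 µM 26 were in library A, and all 6 naive ones were in naive 2.

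Of the genes limma called between 10 and 0.01 µM on the deposited values, 23.3% were higher at 10 µM, against 53.6% with DESeq2 and 56.2% among genes with a mean of at least 20, and for the lower ones RNA of P13.9 cells in the 0.01 µM libraries is a candidate explanation. Of the 454 lower genes, 25.3% were still called lower with the fibroblast-list share subtracted and 41.0% with the added-set share, and 43.2% and 54.8% after rescaling. Plain subtraction lowers all values at 0.01 µM, so it favors this explanation by construction. P13.9 RNA may therefore account for part of the lower genes, but the part depends on how the share is estimated, which keeps it open. Cxcl1, Cxcl2 and Ccl2 stood above their own P13.9 mean at 0.01 µM, which no share of the measured P13.9 profile below its full level can give, and P13.9 cells after contact with T cells were not measured.

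For the opposite shifts of Tbx21 and of Gata3, Maf and Epas1, the share was multiplied by the P13.9 level. This gave at most 1.82% of the drop of Gata3, Maf or Epas1 from 0.01 to 10 µM. The value argues against RNA with the measured P13.9 profile as the source of the drop. P13.9 cells after contact with T cells were not measured, so the test does not cover genes raised in such cells. The lowest 10 µM library stood 13.7 times above the highest 0.01 µM library for Tbx21, against 1.87 times that dilution by P13.9 RNA would give, which argues against dilution as the whole cause. An effect of signal strength stays open and was not tested apart from the dose itself. A difference between runs cannot give the changes called within a run, 2.38 for Tbx21 from 0.01 to 1.0 µM (limma adjusted p = 0.00242) and -2.06 for Maf from 0.1 to 10 µM (adjusted p = 0.00963). Gata3 had -0.95 ± 0.21 (adjusted p = 0.152) and Epas1 -2.43 ± 0.74 (adjusted p = 0.489) from 0.1 to 10 µM in the same run. Neither was called, so a difference between runs is left open for the fall of both. The Gata3 values of that run did not overlap, with 40.8 at most at 10 µM and 61.6 at the lowest at 0.1 µM. The limma comparisons within a run were not in the fixed plan.

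More genes were lower than higher at 10 µM against naive cells on the deposited values, with 42.6% of calls higher, against 54.0% with edgeR. Thinning the activated reads to the naive depth, a test written before its result was seen, moved that share by -7.62 points and away from an even balance. That test kept the genes as first filtered, and 56.7% of calls were higher among genes with a mean of at least 20, so the depth of the naive libraries stays open as a cause. With TMM rescaling 68.2% of the calls were higher, but TMM moved the median of all genes from -0.07 to 0.73, so that the change of balance follows from that shift. Which scaling is right cannot be told from these values, and no biological explanation was tested.

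Other splits of the same 6 libraries are 10 with the real one, too few for a share below 0.05. In each of these comparisons 1 of the 10 splits, the real one, reached the real count, except 1.0 against 0.1 µM, where all 10 gave 0. The real counts and the highest of the other splits were 4145 and 0 at 10 µM against naive cells, 3973 and 1 at 1.0 µM, 4093 and 0 at 0.1 µM and 3588 and 0 at 0.01 µM. They were 592 and 0 for 10 against 0.01 µM, 6 and 0 for 10 against 1.0 µM, 406 and 0 for 0.1 against 0.01 µM and 4826 and 2 for P13.9 against naive cells. For the slope, 1 of 100 splits reached 474, the real one, a share below 0.05, with 0 the highest of the others. Each drawn split mixes libraries of doses that differ, which widens the spread within its groups. Any difference between the groups could therefore give this outcome, so it does not single out a dose trend. For the curvature 3 of 100 splits reached 55, also a share below 0.05, but the highest of the others gave 87, more than the real split. The same limit holds there, and no conclusion on chance is drawn from either count.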
